A study of Mus musculus with 8 samples.

How the data were processed

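Gene expression was measured by RNA-seq in primary CD8+ T cells of C57BL/6 mice, purified from lymph node and spleen, activated with antibodies against CD3 and CD28 and kept for 48 hours with a compound or its vehicle, per the labels' protocols. The groups were DMSO (the vehicle), EnPGC-1, Ctrl PIP and SGC-CBP30, with 2 libraries each and 8 libraries in all. Groups and replicate numbers were taken from the labels. The labels give no doses, and how the cells were purified is not given in the sources used here. RNA was extracted with a column kit (RNeasy) and made into libraries with a strand-marking poly(A) kit (TruSeq Stranded mRNA), per the labels' protocols. Replication-dependent histone messages carry no poly(A) tail, so their counts depend on how the selection worked in each library.

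The authors deposited a table of whole-number counts per gene, listed under Entrez gene IDs, for 45777 genes, with 1 column per library and no pooling. HISAT2, StringTie and DESeq2 and the genome build mm10 are named, per the submitters' processing notes, with no versions or roles. The counter, its strand setting, the annotation and any filter are not given in the sources used here. Overlapping and antisense genes and genes with near-identical copies (Ly6c1 and Ly6c2, the Klra family, the globin genes, the histone genes) may therefore share counts, and their values are uncertain to that extent. The authors also deposited regularized log2 values (rlog, as the name of the table and DESeq2 among the tools tell) of 16442 genes, made over all 8 libraries after a filter that is not given in the sources used here. These log2 values shrink the differences of genes with low counts, and they entered only 1 alternative. Each header name of that table stands 1 column to the left of its values, which was found by correlating its columns with the counts. There were 0 columns of other samples.

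Gene symbols and positions came from a RefSeq gene table on GRCm38.p6, the assembly called mm10, which matched 99.8% of the IDs in the count table. Transcript length and GC content were those of the longest transcript per gene in GENCODE mouse release 21 (the M series, on GRCm38), known for 92.2% of the genes tested.

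Total counts ranged from 38890043 to 55491261 per library. Counts were tested with edgeR's quasi-likelihood test (glmQLFit with robust estimation and glmQLFTest, edgeR 4.0.16 in R 4.3.3) on all 8 libraries, with TMM normalization, filterByExpr by group, group means and no covariates. This left 16750 genes and 4 residual degrees of freedom, shared by all 6 comparisons. Tests were two-sided, and p-values were adjusted over the genes of a comparison by the Benjamini-Hochberg method at 0.05. Levels are CPM (edgeR's cpm function) scaled by the TMM library sizes, and log2 CPM used a prior count of 2. Intervals of log2 fold changes cover the spread between libraries as the model estimates it.

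The design, the tests, 38 gene lists and the rule for named genes were fixed before the data were examined. Lists were written from general knowledge of T cells, mitochondria and metabolism, stress responses and markers of other cell types, and none was chosen by the study on these samples. Each list was tested with limma's camera (limma 3.58.1) with a preset correlation between genes of 0.01, which compares the list with all other genes tested, and Benjamini-Hochberg adjustment over the lists. It was tested again with an estimated correlation and with fry, which asks whether the members move one way on balance and compares them with no other genes. Lists needed at least 3 tested members. The rule for named genes had 3 parts: a fixed set for the EnPGC-1 comparisons, up to 8 genes per direction past the adjusted threshold with at least 5 CPM in the higher group and both libraries of one group above both of the other, and the members with the smallest p of each list described. The middle part named no gene, since no gene passed edgeR's adjusted threshold. Genes named for a DESeq2 call were chosen after their values were seen. Levels in groups at 0 were set against a floor of 3 counts per library.

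Alternative settings chosen at the outset were DESeq2 size factors within edgeR, DESeq2's Wald test (DESeq2 1.42.0), no filter on low counts, the replicate number as a block, only the 4 libraries of a comparison, limma on the authors' rlog values, a log2 fold change of at least 1, each library left out in turn, the estimated correlation and fry. Alternatives chosen after seeing the data were the fits without the first, or without the second, library of both DMSO and EnPGC-1, offsets for transcript length and GC content (smooth trends from mgcv 1.9.3), 1 surrogate variable (sva 3.50.0), the offsets in the fit of 4 libraries, the list tests in the fit of 4 libraries, and the block with the numbers of Ctrl PIP exchanged. Overlap between compounds was set against 20 draws of simulated unchanged groups compared with the same DMSO libraries. The tests were checked on simulated counts with 200 changed genes. Genes of the Y chromosome and Xist were not reported. Some results for other single genes are not reported here.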

Results

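RNA-seq counts were obtained for 8 libraries of mouse CD8+ T cells, the lymphocytes that kill infected and tumour cells, which had been activated through the T cell receptor and kept with a compound for 48 hours. There were 4 groups of 2 libraries each, treated with the vehicle DMSO, EnPGC-1, Ctrl PIP or SGC-CBP30, an inhibitor of the bromodomains of the acetyltransferases CBP and p300. The study concerns an epigenetic route to more mitochondria in T cells, and the comparisons ask what EnPGC-1 did relative to its vehicle, to the compound named as a control and to a CBP/p300 inhibitor. The labels give no doses, so the compounds could not be matched by dose. Total counts of replicates 1 and 2 were 41314599 and 55167278 with DMSO, 38890043 and 55491261 with EnPGC-1, 50545906 and 50734398 with Ctrl PIP, and 53654673 and 52795446 with SGC-CBP30. Between 18348 and 19057 genes were detected per library. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Levels are given as mean CPM ± SD with n = 2 libraries per group, and fold changes as log2 values with their SE.

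The replicates of DMSO and of EnPGC-1 lay far apart. Along the principal component with 49.6% of the variance, replicate 1 of DMSO stood at -68.9 and replicate 2 at 89.6, and the EnPGC-1 libraries stood at -109.8 and 38.1. The Ctrl PIP libraries (47.5 and 22.4) and the SGC-CBP30 libraries (-22.7 and 3.72) lay closer together. Across genes, which are not independent replicates, the log2 CPM of replicates correlated at r = 0.929 for DMSO, 0.929 for EnPGC-1, 0.980 for Ctrl PIP and 0.982 for SGC-CBP30, while replicate 1 of DMSO and replicate 1 of EnPGC-1 correlated at 0.975. The libraries also differed from each other in a relative trend on transcript length. Each gene's log2 CPM was taken as its deviation from the mean over the 8 libraries, for genes with a mean above 3. The Spearman rho between this deviation and length was 0.56 and 0.49 in replicate 1 of DMSO and of EnPGC-1. With SGC-CBP30 it was 0.54 and 0.48. It was -0.61 and -0.52 in replicate 2 of DMSO and of EnPGC-1, and -0.53 and -0.20 with Ctrl PIP. These values set libraries against each other and are not correlations of expression itself with length. Counts of the ribosomal RNA gene Rn18s-rs5 reached 10073 CPM in replicate 2 of DMSO and 9044 CPM in replicate 2 of EnPGC-1, against 1119 to 2311 CPM in the other 6 libraries. The variance between replicates exceeded sampling noise by a median factor of 90.8 in DMSO, 59.6 in EnPGC-1, 11.4 in Ctrl PIP and 11.1 in SGC-CBP30, and 0 pairs of libraries held identical values, so each library counted as 1 replicate.

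**Figure D1:**
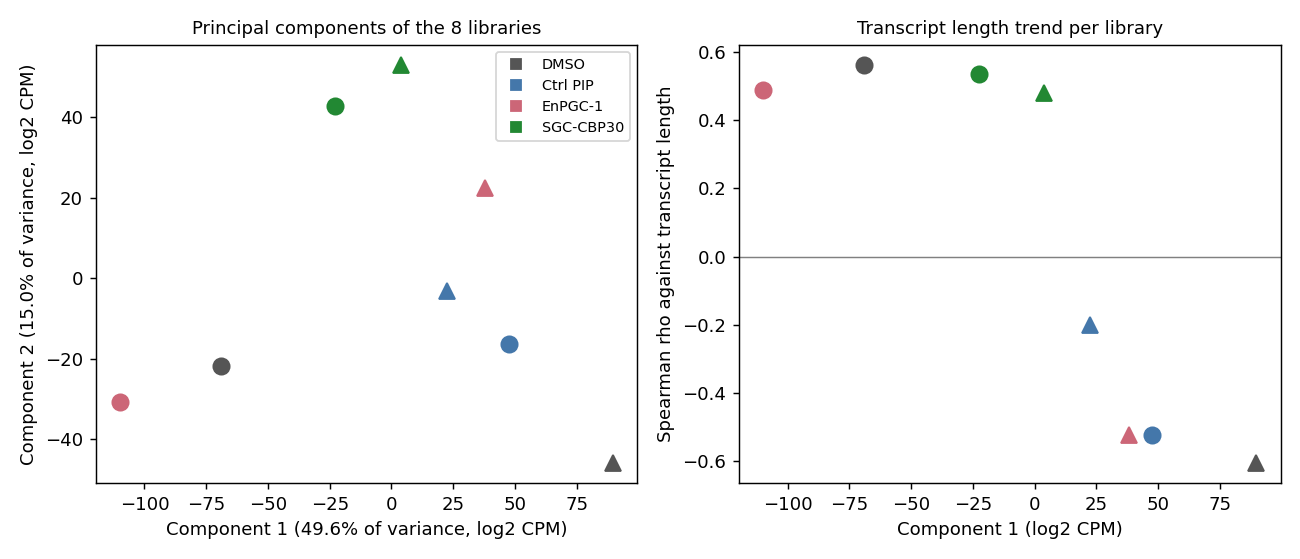
The left panel places the 8 libraries on the principal components of log2 CPM (the first with 49.6% of the variance). The right panel sets the first component against each library's Spearman rho with transcript length. That rho takes each gene's log2 CPM minus its mean over the 8 libraries. Colour marks the group, circles mark replicate 1 and triangles mark replicate 2. The DMSO libraries stand at -68.9 and 89.6 and the EnPGC-1 libraries at -109.8 and 38.1 on the first component.

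This spread set the precision. In counts simulated for EnPGC-1 against DMSO, 200 of 16750 genes were changed. edgeR recovered 0 of the genes changed 2-fold, 58 (29%) of those changed 4-fold and 128 (64%) of those changed 8-fold. The simulation drew genes independently with the spread estimated over all 8 libraries (common coefficient of variation 0.415). The libraries of DMSO and EnPGC-1 alone gave 0.562, so recovery in this comparison may differ from these shares. The median gene's 95% interval reached 0.998 log2 units to either side in that comparison. Intervals cover the spread between libraries and are given where a difference between compounds is described. The 838 genes expected by chance at an unadjusted p under 0.05 assume that the shared spread suits each comparison. It was above that of Ctrl PIP and SGC-CBP30 alone (0.159), so a count under 838 does not show an absence of signal.

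EnPGC-1 was compared with DMSO to find what the compound did relative to its vehicle. Activation and costimulation genes fell together, with 24 of 28 tested members below 0 and a median log2 fold change of -0.64 (camera adjusted p = 4.3e-14, and adjusted p = 0.033 with an estimated correlation). Batf3, a transcription factor of activated lymphocytes, was at 0.449 ± 0.257 CPM against 2.77 ± 0.112 CPM (-2.61, SE 0.54). Slc7a5, a large neutral amino acid transporter, was at 56.1 ± 12.4 against 113 ± 16.2 CPM (-1.01, SE 0.24), and Myc, a transcription factor of growth, at 91.8 ± 8.40 against 177 ± 43.1 CPM (-0.95, SE 0.24). All 34 tested genes of ribosome biogenesis and MYC targets were below 0, with a median of -0.64 (camera adjusted p = 1.4e-22, and adjusted p = 0.38 with an estimated correlation), among them Nop2, a methyltransferase of ribosomal RNA (-0.82, SE 0.26). Cholesterol synthesis genes had a median of -0.63 with 24 of 25 below 0 (camera adjusted p = 1.5e-13, and adjusted p = 0.49 with an estimated correlation).

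Effector molecules were also lower with EnPGC-1 than with DMSO, with 18 of 23 below 0 and a median of -0.39 (camera adjusted p = 3.6e-06, and adjusted p = 0.32 with an estimated correlation). Gzmb, which encodes the cytotoxic protease granzyme B, was at 81.5 ± 2.62 against 355 ± 191 CPM, a log2 fold change of -2.12 (95% interval -3.10 to -1.14). Its edgeR quasi-likelihood adjusted p (Benjamini-Hochberg) was 0.998, and 0.00336 to 1 over the alternatives. Ifng, which encodes interferon gamma, was at 4.53 ± 1.66 against 10.3 ± 3.22 CPM (-1.18, SE 0.40), and Prf1, which encodes the pore-forming perforin, had a log2 fold change of 0.09 (SE 0.31). Chemokine, cytokine and receptor genes had a median of -0.31 with 24 of 38 below 0 (camera adjusted p = 5.5e-04, and adjusted p = 0.49 with an estimated correlation). The chemokine call was lost without replicate 1 of DMSO or replicate 2 of EnPGC-1 (camera adjusted p = 0.63 and 0.66). Of the inhibitory receptors and exhaustion factors, 17 of 22 were below 0 with a median of -0.40 (camera adjusted p = 0.003, and adjusted p = 0.41 with an estimated correlation), and this was lost without the same libraries (camera adjusted p = 0.23 and 0.066). With both first or both second libraries of DMSO and EnPGC-1 left out, chemokine genes were not called (camera adjusted p = 0.15 and 0.12), and inhibitory receptors were lower only without the second (camera adjusted p = 0.22 and 0.011). Pdcd1, which encodes the inhibitory receptor PD-1, had a log2 fold change of -0.06 (SE 0.36), and Tcf7, a transcription factor of naive and memory T cells, of 0.40 (SE 0.33). CD8 T cell identity genes had a median of -0.01 (camera adjusted p = 0.89) and B cell markers a median of 0.03 (camera adjusted p = 0.68). The identity genes were called lower without both second libraries of DMSO and EnPGC-1, but not without both first.

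Among the genes of mitochondria and metabolism, Ppargc1a, the transcriptional coactivator PGC-1 alpha, had 14 and 0 counts in the DMSO libraries, 74 and 10 with EnPGC-1, 0 and 0 with Ctrl PIP, and 0 and 3 with SGC-CBP30. Against DMSO its log2 fold change was 2.57 (95% interval -2.61 to 7.75), so a difference was not resolved given the spread between libraries. Its relative Ppargc1b was at 21.3 ± 15.9 CPM against 18.9 ± 11.8 CPM (0.17, SE 0.63), and Pprc1, the third member of the family, at -0.46 (SE 0.33). The log2 fold changes of Tfam, Nrf1 and Esrra, transcription factors of mitochondrial genes, were -0.26 (SE 0.38), -0.10 (SE 0.17) and -0.20 (SE 0.23). Cpt1a, the enzyme that commits fatty acids to mitochondrial oxidation, was at 162 ± 11.4 against 106 ± 55.8 CPM (0.62, SE 0.35), and Cpt1b and Cpt2, enzymes of the same carnitine shuttle, had -0.17 (SE 1.01) and -0.16 (SE 0.45). The acetyltransferase genes Crebbp and Ep300 had 0.21 (SE 0.65) and 0.16 (SE 0.70). The 24 mitochondrial biogenesis regulators had a median of -0.09 and a mean of 0.02 (camera adjusted p = 0.56), mitochondrially encoded genes a median of -0.04 (camera adjusted p = 0.73), and fatty acid oxidation genes a median of -0.09 (camera adjusted p = 0.78). Fatty acid oxidation genes were called higher without replicate 1 of EnPGC-1 and lower without replicate 2 (camera adjusted p = 0.048 and 0.032).

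Lists of mitochondria and growth were next compared between EnPGC-1 and DMSO. All 36 complex I subunits were below 0, with a median of -0.40 (camera adjusted p = 1.1e-04, and adjusted p = 0.74 with an estimated correlation). Without replicate 2 of DMSO the list was higher (camera adjusted p = 8.2e-06), and without replicate 1 of EnPGC-1 it was not called (camera adjusted p = 0.77). Of 78 mitochondrial ribosomal proteins 77 were below 0, with a median of -0.45 (camera adjusted p = 4.4e-10, and adjusted p = 0.74 with an estimated correlation). They were higher without replicate 2 of DMSO (camera adjusted p = 0.0016) and not called without replicate 1 of EnPGC-1 (camera adjusted p = 0.30). Proliferation genes were all below 0 (40 members, median -0.47, camera adjusted p = 1.1e-07, and adjusted p = 0.74 with an estimated correlation), as were 21 of 23 glycolysis genes (median -0.74, camera adjusted p = 7.2e-06, and adjusted p = 0.71 with an estimated correlation). Without replicate 2 of DMSO or replicate 1 of EnPGC-1, neither list was called (camera adjusted p = 0.82 and 0.20 for proliferation, 0.63 and 0.26 for glycolysis). Replicates of the same number in DMSO and EnPGC-1 deviated together, so fits without both first or both second libraries were added after seeing the data. These fits compare 1 library with 1, and take the spread from Ctrl PIP and SGC-CBP30 alone. The common coefficient of variation of those 2 groups was 0.159, against 0.562 for DMSO and EnPGC-1. Mitochondrial ribosomal proteins, proliferation genes and glycolysis genes were called lower both times. Complex I subunits were called lower without the first libraries and not called without the second. Such calls cannot show that a list would fall again in new libraries. Hk2, the hexokinase of activated T cells, was at 15.5 ± 3.78 against 48.9 ± 34.9 CPM (-1.66, SE 0.51), and Mcm2, a subunit of the replicative helicase, had -0.72 (SE 0.26).

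In the gene-wise test of EnPGC-1 against DMSO, edgeR's quasi-likelihood test called 0 genes higher and 0 lower, with 134 higher and 304 lower at an unadjusted p under 0.05 (fewer than the 838 expected by chance). DESeq2 called 5 higher and 13 lower. The 5 higher genes, chosen after their values were seen, were Uchl1, a deubiquitinating enzyme of neurons (9.52 ± 6.66 against 1.53 ± 0.124 CPM), Amt, an enzyme of glycine cleavage (6.95 ± 1.17 against 2.65 ± 0.224 CPM), Agbl3, Gm11127, which had counts in 1 EnPGC-1 library only (6.67 CPM in replicate 2), and Il4i1b. Of the lists, camera called 1 higher and 19 lower, and the 1 still called with an estimated correlation was activation and costimulation genes. Adjusted over the list alone, edgeR called 4 activation genes, 1 effector gene, 1 chemokine gene and 1 cholesterol synthesis gene lower, where DESeq2 called 1 of each. Without the first libraries of DMSO and EnPGC-1, edgeR called 377 genes higher and 718 lower, and without the second libraries 0 and 0, both fits chosen after seeing the data.

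EnPGC-1 was next compared with Ctrl PIP, the compound named as its control. Activation and costimulation genes were again lower, with 23 of 28 below 0 and a median of -0.55 (camera adjusted p = 6.8e-09, and adjusted p = 0.086 with an estimated correlation). Batf3 had a log2 fold change of -2.69 (SE 0.54) from 2.93 ± 0.728 CPM with Ctrl PIP, and Slc7a5 of -1.15 (SE 0.24) from 124 ± 21.4 CPM. All 34 genes of ribosome biogenesis and MYC targets were below 0, with a median of -0.77 (camera adjusted p = 9.8e-22, and adjusted p = 0.61 with an estimated correlation). Cad, the enzyme that starts pyrimidine synthesis, was at 113 ± 29.0 against 232 ± 34.8 CPM (-1.03, SE 0.24), Srm, spermidine synthase, at 39.6 ± 5.87 against 109 ± 7.07 CPM (-1.45, SE 0.38), and Myc at 91.8 ± 8.40 against 139 ± 20.7 CPM (-0.59, 95% interval -1.16 to -0.03). Proliferation genes were all below 0 (40 members, median -0.70, camera adjusted p = 2.8e-14, and adjusted p = 0.61 with an estimated correlation), with Mcm2 at 113 ± 19.4 against 230 ± 5.85 CPM. Their call was lost without replicate 1 of EnPGC-1 (camera adjusted p = 0.088). Cholesterol synthesis genes had a median of -0.53 with 24 of 25 below 0 (camera adjusted p = 2e-09, and adjusted p = 0.61 with an estimated correlation). Glycolysis genes had a median of -0.70 with 21 of 23 below 0 (camera adjusted p = 1.5e-06, and adjusted p = 0.61 with an estimated correlation). Hk2 was at 15.5 ± 3.78 against 54.8 ± 6.47 CPM (-1.82, SE 0.51).

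The effector genes of EnPGC-1 and Ctrl PIP did not all go one way. Gzmb was at 81.5 ± 2.62 against 227 ± 63.5 CPM, a log2 fold change of -1.48 (95% interval -2.44 to -0.52), while Gzma, which encodes granzyme A, was at 16.5 ± 5.25 against 7.87 ± 2.25 CPM (1.07, SE 0.32). Effector molecules had a median of -0.36 with 14 of 23 below 0 (camera adjusted p = 0.021, and adjusted p = 0.61 with an estimated correlation), which was not called without replicate 1 or replicate 2 of EnPGC-1 (camera adjusted p = 0.051 and 0.076). Ccr2, a chemokine receptor of effector cells, had a log2 fold change of -1.49 (SE 0.46). Ifng had a log2 fold change of -0.78 (SE 0.40), Prf1 of 0.14 (SE 0.31), Pdcd1 of 0.12 (SE 0.36) and Tcf7 of 0.55 (SE 0.33). Klf2, a transcription factor that keeps T cells quiescent and recirculating, was at 340.4 ± 40.1 against 212 ± 8.83 CPM (0.68, SE 0.20). Beside these groups, B cell markers were higher with EnPGC-1 than with Ctrl PIP, with 18 of 18 above 0 and a median of 1.34 (camera adjusted p = 1.5e-07, and adjusted p = 0.61 with an estimated correlation). Pax5, the transcription factor of the B cell lineage, was at 3.05 ± 1.69 against 0.721 ± 0.338 CPM, while CD8 T cell identity genes had a median of 0.12 (camera adjusted p = 0.29) and were called higher without replicate 1 of EnPGC-1 (camera adjusted p = 0.021). Erythroid and platelet markers were higher too, with a median of 1.28 and 7 of 7 above 0 (camera adjusted p = 0.0037, and adjusted p = 0.61 with an estimated correlation), not called without replicate 2 of Ctrl PIP (camera adjusted p = 0.056). Myeloid markers had a median of 1.21, or 1.09 with members at 0 set to their bounds (camera adjusted p = 0.089), and were called higher without replicate 2 of EnPGC-1 (camera adjusted p = 7.8e-04). NK cell markers had a median of -0.76 with 8 of 12 below 0 (camera adjusted p = 0.0023, and adjusted p = 0.47 with an estimated correlation), not called without replicate 2 of EnPGC-1 (camera adjusted p = 0.059).

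For mitochondrial genes, Ppargc1a was detected with EnPGC-1 (74 and 10 counts) and had 0 and 0 counts with Ctrl PIP. Its EnPGC-1 mean of 0.991 CPM was at least 16.8-fold higher than the Ctrl PIP floor of 0.0589 CPM set by 3 counts per library, with bounds of 30.5 and 3.15 for the 2 EnPGC-1 libraries taken alone. These bounds allow for counting error in the Ctrl PIP libraries only and take the EnPGC-1 counts as exact. They leave out the spread between libraries, and DMSO replicate 1 had 14 counts of the same gene. The log2 fold changes against Ctrl PIP were 0.63 (SE 0.63) for Ppargc1b, -0.57 (SE 0.33) for Pprc1, -0.18 (SE 0.38) for Tfam, -0.02 (SE 0.17) for Nrf1 and -0.08 (SE 0.23) for Esrra. Cpt1a was at 162 ± 11.4 against 86.6 ± 5.21 CPM (0.90, 95% interval 0.05 to 1.75, edgeR quasi-likelihood adjusted p = 0.812 by Benjamini-Hochberg, and 0.00799 to 1 over the alternatives). Cpt1b had 0.29 (SE 1.01), Cpt2 had -0.25 (SE 0.45), Crebbp had 0.61 (SE 0.66) and Ep300 had 0.74 (SE 0.70). The mitochondrial biogenesis regulators had a median of -0.05 and a mean of 0.31, with 15 of 24 below 0 (camera adjusted p = 0.71). Complex I subunits had a median of -0.30 with 35 of 36 below 0 (camera adjusted p = 0.0021, and adjusted p = 0.76 with an estimated correlation). Mitochondrial ribosomal proteins had a median of -0.38 with 75 of 78 below 0 (camera adjusted p = 8.4e-08, and adjusted p = 0.73 with an estimated correlation). Without replicate 1 of EnPGC-1 neither was called (camera adjusted p = 0.69 and 0.26), and without replicate 1 of Ctrl PIP complex I was not (camera adjusted p = 0.057). Mitochondrially encoded genes had a median of -0.22 (camera adjusted p = 0.10) and fatty acid oxidation genes of -0.06 (camera adjusted p = 0.59), the latter called lower without replicate 2 of EnPGC-1 (camera adjusted p = 0.027).

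In the gene-wise test against Ctrl PIP, edgeR's quasi-likelihood test called 0 genes higher and 0 lower, with 286 higher and 464 lower at an unadjusted p under 0.05 (fewer than the 838 expected by chance), and DESeq2 called 8 higher and 25 lower. Genes called by DESeq2, chosen after their values were seen, included Lad1, a filament anchor of epithelia (17.0 ± 5.94 against 68.2 ± 13.8 CPM), Shmt1, a serine hydroxymethyltransferase (17.5 ± 2.09 against 51.1 ± 6.26 CPM), and, on the higher side, Rsrp1 (488 ± 22.0 against 289 ± 24.1 CPM). Camera called 3 lists higher and 18 lower, and 0 of them with an estimated correlation. Adjusted over the list alone, edgeR called 3 activation genes and 1 cholesterol synthesis gene lower, and DESeq2 called 3 and 1. When the first libraries of DMSO and EnPGC-1 were left out, the edgeR counts were 5 higher and 36 lower, and without the second 2430 higher and 2753 lower.

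Ctrl PIP against DMSO measured the background response to the control compound. B cell markers were lower with Ctrl PIP, with a median of -1.25 and 18 of 18 below 0 (camera adjusted p = 4.2e-16, and adjusted p = 0.63 with an estimated correlation), among them Pax5 (-2.21, SE 0.84) and Cd74, the invariant chain of MHC class II (-0.55, SE 0.23). Myeloid markers had a median of -1.16 with 11 of 14 below 0 (camera adjusted p = 2.7e-05, and adjusted p = 0.65 with an estimated correlation), which was not called without replicate 2 of DMSO (camera adjusted p = 0.072). Dendritic cell markers had a median of -0.50 (camera adjusted p = 0.025, and adjusted p = 0.63 with an estimated correlation), not called without either DMSO library or replicate 2 of Ctrl PIP (camera adjusted p = 0.18, 0.27 and 0.12). The 19 of 28 activation genes below 0 gave a median of -0.13 (camera adjusted p = 0.55), and ribosome biogenesis and MYC targets a median of 0.04 (camera adjusted p = 0.068). The latter list was called lower without replicate 1 of DMSO (camera adjusted p = 9.8e-04) and higher without replicate 2 of DMSO or replicate 1 of Ctrl PIP (camera adjusted p = 3.4e-08 and 0.031). Proliferation genes had a median of 0.24 with 39 of 40 above 0 (camera adjusted p = 1.2e-06, and adjusted p = 0.86 with an estimated correlation), not called without replicate 1 of DMSO (camera adjusted p = 0.31). Effector molecules had a median of -0.24 with 19 of 23 below 0 (camera adjusted p = 0.018, and adjusted p = 0.65 with an estimated correlation), a call lost without replicate 1 of DMSO, replicate 2 of DMSO or replicate 2 of Ctrl PIP (camera adjusted p = 0.077, 0.22 and 0.31).

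Mitochondrially encoded genes were higher with Ctrl PIP than with DMSO, with 12 of 13 above 0 and a median of 0.25 (camera adjusted p = 0.0014, and adjusted p = 0.65 with an estimated correlation), and were not called without replicate 2 of DMSO (camera adjusted p = 0.24). The mitochondrial biogenesis regulators had a median of -0.03 (camera adjusted p = 0.85). Complex I subunits had a median of -0.12 (camera adjusted p = 0.85), and were called lower without replicate 1 of DMSO (camera adjusted p = 9.5e-16) and higher without replicate 2 (camera adjusted p = 9.1e-11). In the gene-wise test edgeR called 0 genes higher and 0 lower, with 39 higher and 61 lower at an unadjusted p under 0.05 (fewer than the 838 expected by chance). DESeq2 called 0 higher and 1 lower, the predicted gene Gm15564, which had 0 and 96.9 CPM in the DMSO libraries and 0 in both Ctrl PIP libraries and was chosen after its values were seen. Camera called 4 lists higher and 5 lower, and 0 with an estimated correlation. When the first libraries of DMSO and EnPGC-1 were left out, the edgeR counts were 1 higher and 0 lower, and without the second 1164 higher and 1201 lower.

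SGC-CBP30 was compared with DMSO as the inhibitor of CBP and p300. Effector molecules fell together, with 21 of 23 below 0 and a median of -0.99 (camera adjusted p = 3.7e-19, and adjusted p = 0.044 with an estimated correlation). Gzmb was at 39.0 ± 3.74 against 355 ± 191 CPM (-3.19, 95% interval -4.21 to -2.16), and Xcl1, a chemokine of activated CD8+ T cells, at 5.38 ± 0.445 against 24.3 ± 13.3 CPM (-2.18, SE 0.42). Activation and costimulation genes fell as well, with 24 of 28 below 0 and a median of -0.64 (camera adjusted p = 5.2e-15, and adjusted p = 0.030 with an estimated correlation). Among them were Myc at 67.0 ± 5.78 against 177 ± 43.1 CPM (-1.40, 95% interval -1.98 to -0.83) and Batf3 at 0.306 ± 0.0685 against 2.77 ± 0.112 CPM (-3.17, SE 0.55). All 34 genes of ribosome biogenesis and MYC targets were below 0, with a median of -0.69 (camera adjusted p = 1.6e-17, and adjusted p = 0.30 with an estimated correlation). Chemokine, cytokine and receptor genes had a median of -0.66 with 30 of 38 below 0, or -0.59 with a member at 0 set to its bound (camera adjusted p = 1.6e-09, and adjusted p = 0.26 with an estimated correlation). NK cell markers, several of which activated CD8+ T cells share, had a median of -1.09, or -0.89 with members at 0 set to their bounds (camera adjusted p = 1.9e-04, and adjusted p = 0.17 with an estimated correlation), not called without replicate 1 of DMSO (camera adjusted p = 0.066).

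Markers of other cell types were compared next. B cell markers were lower with SGC-CBP30 than with DMSO, with 16 of 18 below 0 and a median of -2.17 (camera adjusted p = 4e-15, and adjusted p = 0.28 with an estimated correlation). Cd74 was at 26.0 ± 3.96 against 69.0 ± 0.467 CPM (-1.41, SE 0.23), and Cd22, a B cell surface lectin, at 0.989 ± 0.397 against 6.25 ± 2.53 CPM (-2.66, SE 0.54). Myeloid markers had a median of -1.65 with 12 of 14 below 0 (camera adjusted p = 7.7e-05, and adjusted p = 0.46 with an estimated correlation). Erythroid and platelet markers had a median of -1.82 with 7 of 7 below 0 (camera adjusted p = 0.0065, and adjusted p = 0.28 with an estimated correlation), and dendritic cell markers a median of -0.57 (camera adjusted p = 0.018, and adjusted p = 0.28 with an estimated correlation). Neither was called without replicate 1 of DMSO (camera adjusted p = 0.24 and 0.22), replicate 2 of EnPGC-1 (camera adjusted p = 0.094 and 0.060) or replicate 2 of SGC-CBP30 (camera adjusted p = 0.46 and 0.13).

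Genes of metabolism and mitochondria were also compared between SGC-CBP30 and DMSO. Cholesterol synthesis genes had a median of -0.56 with 25 of 25 below 0 (camera adjusted p = 3.5e-09, and adjusted p = 0.46 with an estimated correlation). Complex I subunits had a median of -0.59 with 36 of 36 below 0 (camera adjusted p = 3.9e-06, and adjusted p = 0.63 with an estimated correlation). Mitochondrial ribosomal proteins had a median of -0.57 with 78 of 78 below 0 (camera adjusted p = 1.6e-13, and adjusted p = 0.61 with an estimated correlation). Without replicate 2 of DMSO complex I subunits were higher (camera adjusted p = 0.0081), and mitochondrial ribosomal proteins and cholesterol synthesis were not called (camera adjusted p = 0.33 and 0.10). Mitochondrially encoded genes had a median of 0.24 (camera adjusted p = 0.022, and adjusted p = 0.61 with an estimated correlation), not called without replicate 1 of DMSO or replicate 2 of SGC-CBP30 (camera adjusted p = 0.074 and 0.88). The mitochondrial biogenesis regulators had a median of -0.15 (camera adjusted p = 0.42), fatty acid oxidation genes of 0.04 with a mean of -0.11 (camera adjusted p = 0.83) and CD8 T cell identity genes of -0.24 (camera adjusted p = 0.054). Without replicate 2 of DMSO, fatty acid oxidation genes were called higher and CD8 T cell identity genes lower (camera adjusted p = 0.045 and 0.035), the latter also without replicate 2 of EnPGC-1 or replicate 1 of SGC-CBP30 (camera adjusted p = 0.034 and 0.011).

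In the gene-wise test of SGC-CBP30 against DMSO, edgeR's quasi-likelihood test called 0 genes higher and 0 lower, with 263 higher and 472 lower at an unadjusted p under 0.05 (fewer than the 838 expected by chance), and DESeq2 called 7 higher and 52 lower. Among the DESeq2 calls, chosen after their values were seen, Prrt2 was at 13.8 ± 0.263 against 5.45 ± 1.11 CPM, Ifngr2, a chain of the interferon gamma receptor, at 33.1 ± 1.35 against 14.0 ± 0.715 CPM, and Ly6c2, a surface protein of activated and memory CD8+ T cells, at 73.5 ± 20.2 against 454 ± 190.0 CPM. Adjusted over the list alone, edgeR called 8 effector, 7 activation, 7 chemokine, 5 B cell and 1 MYC target gene lower, and DESeq2 called 6, 4, 5, 4 and 1. Camera called 1 list higher and 18 lower, and 0 higher and 2 lower with an estimated correlation. Without the first libraries of DMSO and EnPGC-1 edgeR called 3089 genes higher and 3225 lower, and without the second 4 higher and 11 lower.

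SGC-CBP30 against Ctrl PIP compared the inhibitor with the control compound, the groups whose replicates lay closest. The 2 groups stood on opposite sides of the transcript length trend, with rho 0.54 and 0.48 for SGC-CBP30 and -0.53 and -0.20 for Ctrl PIP. That trend may contribute to the list differences given here. With offsets for length and GC content camera also called 16 lists lower. Activation and costimulation genes fell together, with 24 of 28 below 0 and a median of -0.69 (camera adjusted p = 1.3e-12, and adjusted p = 0.043 with an estimated correlation). Batf3 had a log2 fold change of -3.25 (SE 0.55), and Zbtb32, a zinc finger repressor of activated lymphocytes, was at 10.8 ± 1.74 against 40.7 ± 0.162 CPM (-1.92, SE 0.42). Effector molecules had a median of -0.92 with 20 of 23 below 0 (camera adjusted p = 7.1e-13, and adjusted p = 0.11 with an estimated correlation). Gzmb was at 39.0 ± 3.74 against 227 ± 63.5 CPM (-2.54, 95% interval -3.54 to -1.55) and Xcl1 at 5.38 ± 0.445 against 18.3 ± 4.44 CPM (-1.77, SE 0.41). Ccr2 was at 3.58 ± 0.585 against 16.4 ± 2.36 CPM (-2.19, SE 0.47). Genes of ribosome biogenesis and MYC targets had a median of -0.71 with 33 of 34 below 0 (camera adjusted p = 1.8e-22, and adjusted p = 0.37 with an estimated correlation). Mitochondrial ribosomal proteins had a median of -0.48 with 78 of 78 below 0 (camera adjusted p = 4.6e-13, and adjusted p = 0.67 with an estimated correlation). Complex I subunits had a median of -0.44 (camera adjusted p = 1.7e-05, and adjusted p = 0.67 with an estimated correlation), and the mitochondrial biogenesis regulators a median of 0.00, or -0.02 with Ppargc1a at its bound (camera adjusted p = 0.55). B cell markers had a median of -0.88 with 15 of 18 below 0 (camera adjusted p = 0.0068, and adjusted p = 0.67 with an estimated correlation), not called without replicate 1 of Ctrl PIP or replicate 2 of SGC-CBP30 (camera adjusted p = 0.63 and 0.49). NK cell markers had a median of -1.42 with 11 of 12 below 0, or -1.15 with members at 0 set to their bounds (camera adjusted p = 2e-05, and adjusted p = 0.11 with an estimated correlation).

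In the gene-wise test of SGC-CBP30 against Ctrl PIP over all 8 libraries, edgeR's quasi-likelihood test called 0 genes higher and 0 lower, with 239 higher and 429 lower at an unadjusted p under 0.05 (fewer than the 838 expected by chance), and DESeq2 called 6 higher and 24 lower. The common coefficient of variation was 0.415 over all 8 libraries and 0.159 over these 4. The p-values of edgeR's fit of all 8 libraries may therefore be too large here. With only the 4 libraries of these groups edgeR called 1053 higher and 1241 lower. Genes called in that fit, chosen after their values were seen, included Tubb2b, a beta tubulin, on the higher side (40.1 ± 0.756 against 9.97 ± 2.46 CPM). In the same fit the calls held 27 genes of ribosome biogenesis and MYC targets and 37 mitochondrial ribosomal proteins, all of them lower. They also held 11 activation genes, 9 effector genes and 10 cholesterol synthesis genes, again all lower. Over all genes that fit called 1241 of 16750 lower. These list counts were not corrected for transcript length or GC content. The genes called higher in the 4-library fit had longer transcripts (median 6020 bases) than those called lower (2029 bases), and with the offsets for length and GC content that fit called 615 higher and 854 lower. Adjusted over the list alone, edgeR over all 8 libraries called 7 effector, 4 activation and 4 chemokine genes lower, and DESeq2 called 2, 2 and 3. Camera called 0 lists higher and 16 lower, and 1 lower with an estimated correlation. Without the first libraries of DMSO and EnPGC-1 edgeR called 1036 higher and 1220 lower, and without the second 850 higher and 1016 lower.

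EnPGC-1 was compared directly with SGC-CBP30, to set its response beside that of a CBP/p300 inhibitor. Effector molecules were higher with EnPGC-1 than with SGC-CBP30, with 20 of 23 above 0 and a median of 0.49 (camera adjusted p = 7.5e-10, and adjusted p = 0.19 with an estimated correlation). Gzmb differed by 1.06 log2 units (95% interval 0.11 to 2.02) and Xcl1 by 1.86 (0.87 to 2.85). Xcl1 was at 19.6 ± 2.50 against 5.38 ± 0.445 CPM, and Nkg7, a cytotoxic granule protein, was at 136 ± 42.8 against 70.8 ± 4.25 CPM. Activation and costimulation genes had a median of 0.12 (camera adjusted p = 0.29) and ribosome biogenesis and MYC targets a median of -0.03 (camera adjusted p = 0.90). Myc differed by 0.45 log2 units with an interval of -0.11 to 1.02, which leaves both no difference and a 2-fold difference open. Proliferation genes were lower with EnPGC-1, with 40 of 40 below 0 and a median of -0.53 (camera adjusted p = 9e-15, and adjusted p = 0.68 with an estimated correlation). Glycolysis genes had a median of -0.43 with 21 of 23 below 0 (camera adjusted p = 8.8e-05, and adjusted p = 0.72 with an estimated correlation). Mki67, the proliferation antigen Ki-67, was at 528 ± 205 against 1076 ± 215 CPM (-1.03, SE 0.32). Both calls were lost without replicate 1 of EnPGC-1 (camera adjusted p = 0.96 and 0.80).

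B cell markers were higher with EnPGC-1 than with SGC-CBP30, with a median of 2.22 and 16 of 18 above 0 (camera adjusted p = 7.2e-26, and adjusted p = 0.31 with an estimated correlation). Erythroid and platelet markers had a median of 2.39 with 7 of 7 above 0 (camera adjusted p = 7.5e-10, and adjusted p = 0.16 with an estimated correlation). Cd74 was at 59.2 ± 2.49 against 26.0 ± 3.96 CPM (1.19, 95% interval 0.63 to 1.74), and the globin gene Hba-a1 differed by 2.46 log2 units (SE 0.65). Myeloid markers had a median of 2.03 with 12 of 14 above 0, or 1.51 with members at 0 set to their bounds (camera adjusted p = 8.8e-05, and adjusted p = 0.68 with an estimated correlation), which was not called without replicate 1 of EnPGC-1 (camera adjusted p = 0.73). CD8 T cell identity genes had a median of 0.21 (camera adjusted p = 0.034, and adjusted p = 0.72 with an estimated correlation). That call was lost without replicate 2 of EnPGC-1, either Ctrl PIP library or replicate 2 of SGC-CBP30 (camera adjusted p = 0.83, 0.057, 0.065 and 0.36).

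Of the mitochondrial genes, Ppargc1a had 74 and 10 counts with EnPGC-1 and 0 and 3 with SGC-CBP30. The log2 differences of the other fixed genes were 0.42 (SE 0.63) for Ppargc1b, 0.37 (SE 0.33) for Pprc1, 0.17 (SE 0.38) for Tfam, -0.08 (SE 0.17) for Nrf1, 0.12 (SE 0.23) for Esrra, 0.07 (SE 0.35) for Cpt1a, 0.38 (SE 1.01) for Cpt1b, -0.29 (SE 0.45) for Cpt2, -0.36 (SE 0.65) for Crebbp and -0.34 (SE 0.70) for Ep300. Ifng was at 4.53 ± 1.66 against 2.52 ± 0.343 CPM (0.85, SE 0.40), and Prf1, Pdcd1 and Tcf7 had 0.49 (SE 0.31), -0.07 (SE 0.36) and 0.05 (SE 0.33). Cpt1a stood at 162 ± 11.4 CPM with EnPGC-1 and 154 ± 1.17 CPM with SGC-CBP30. The mitochondrial biogenesis regulators had a median of 0.01 (camera adjusted p = 0.77), complex I subunits of 0.16 (camera adjusted p = 0.27), and mitochondrially encoded genes of -0.22 (camera adjusted p = 0.027, and adjusted p = 0.71 with an estimated correlation). Complex I was called higher without replicate 1 of EnPGC-1 and lower without replicate 2 (camera adjusted p = 2.1e-06 and 0.032). The call of mitochondrially encoded genes was lost without either EnPGC-1 library or replicate 2 of SGC-CBP30 (camera adjusted p = 0.24, 0.11 and 0.97). In the gene-wise test edgeR called 0 genes higher and 0 lower, with 184 higher and 156 lower at an unadjusted p under 0.05 (fewer than the 838 expected by chance), and DESeq2 called 8 higher and 1 lower. The gene called lower was the predicted gene Gm7030, at 0 in both EnPGC-1 libraries and at 6.15 and 0 CPM with SGC-CBP30, and among those higher was Mt1, a metallothionein (26.5 ± 8.55 against 4.14 ± 1.23 CPM), both chosen after their values were seen. Adjusted over the list alone, edgeR called 2 B cell and 4 erythroid markers higher, and DESeq2 called 1 B cell marker, 1 effector gene and 2 chemokine genes. Camera called 6 lists higher and 4 lower, and 0 with an estimated correlation. Without the first libraries of DMSO and EnPGC-1 edgeR called 0 higher and 1 lower, and without the second 344 higher and 539 lower.

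**Figure D2:**
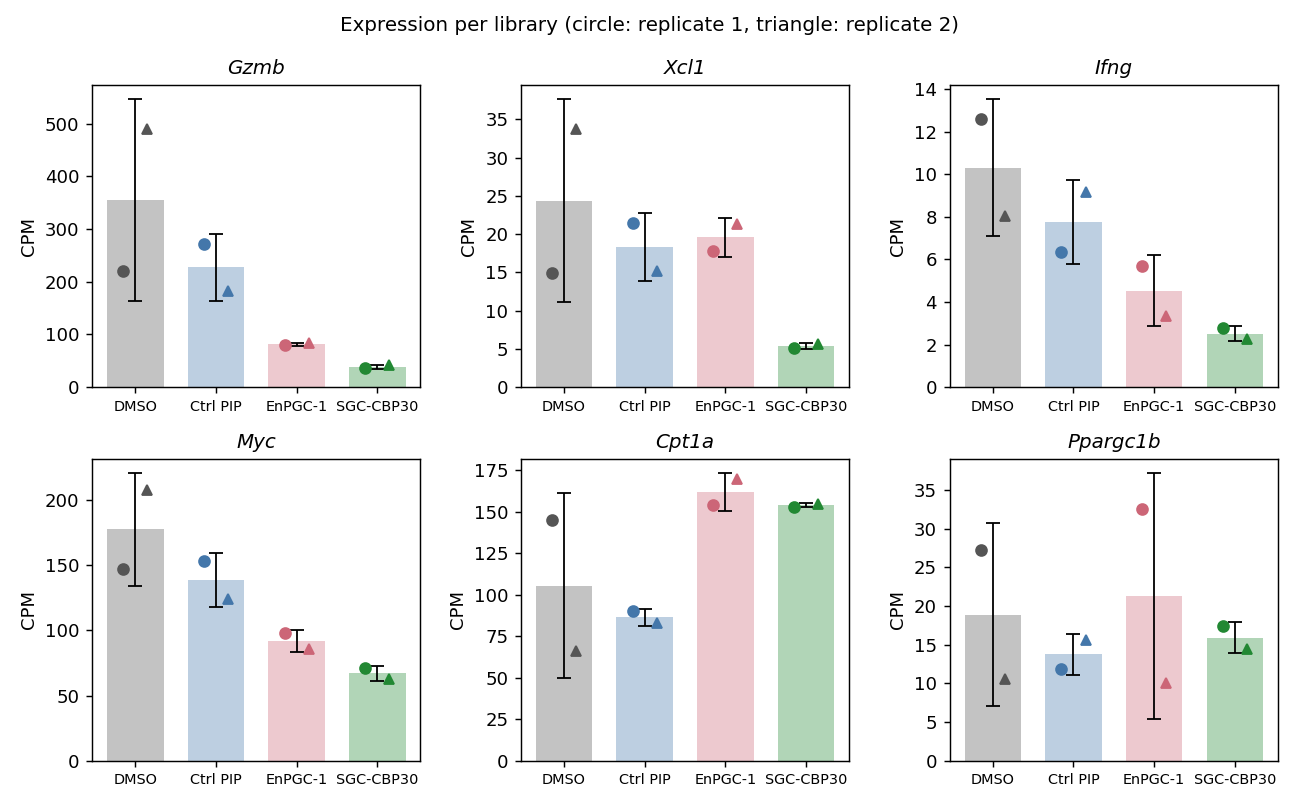
CPM of Gzmb, Xcl1, Ifng, Myc, Cpt1a and Ppargc1b in each library, with bars for the mean of a group, error bars for the SD (n = 2), circles for replicate 1 and triangles for replicate 2. Gzmb stood at 81.5 ± 2.62 CPM with EnPGC-1 and 39.0 ± 3.74 CPM with SGC-CBP30, and the DMSO libraries spread around 355 ± 191 CPM.

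**Figure D3:**
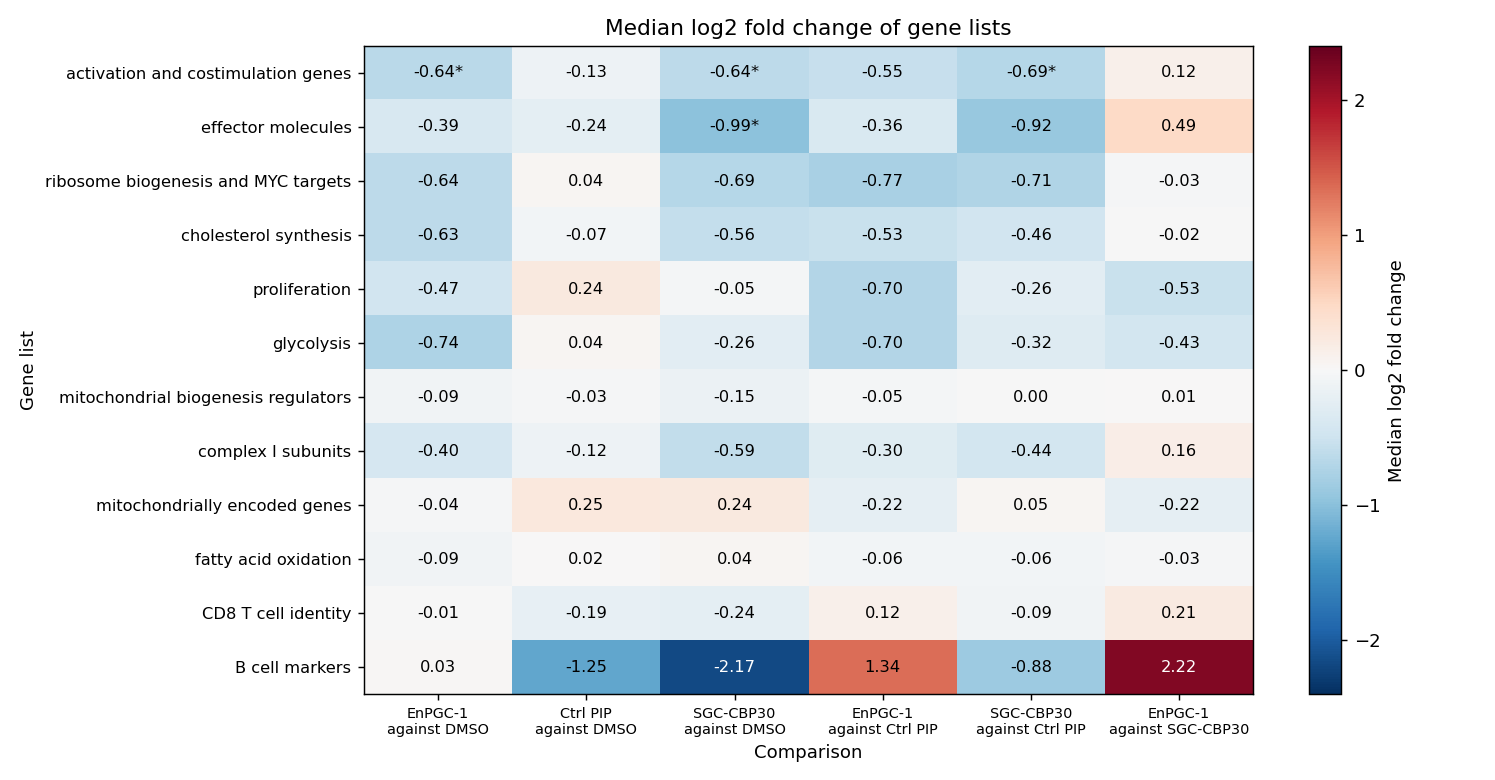
Median log2 fold change (colour and number) of 12 gene lists in the 6 comparisons, with an asterisk where camera's adjusted p with an estimated correlation passed 0.05. Activation and costimulation genes stood at -0.64, -0.64 and -0.69 in the comparisons with an asterisk, and B cell markers ranged from -2.17 to 2.22.

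The responses to the compounds were compared across genes. Against DMSO, log2 fold changes of EnPGC-1 and SGC-CBP30 correlated at r = 0.423 (covariance 0.411), those of EnPGC-1 and Ctrl PIP at 0.153 (covariance 0.147), and those of Ctrl PIP and SGC-CBP30 at 0.516 (covariance 0.572). Simulated unchanged groups set against the same DMSO libraries gave r = 0.126 (0.0643 to 0.170 over 20 draws) and a covariance of 0.0674. The simulation may understate what the shared DMSO libraries add, since DMSO replicates varied most (median factor 90.8 over sampling noise). Whether the observed values exceed that part is therefore not settled. The 2 DMSO libraries are too few to give each compound its own controls. edgeR shared 0 calls between any pair of compounds, and 0 were due to independent lists. Both counts were fixed in advance, since it called 0 genes in each comparison, so they say nothing about overlap. In the comparisons that share no library, EnPGC-1 minus DMSO correlated with SGC-CBP30 minus Ctrl PIP at r = 0.751 over 9299 genes, and EnPGC-1 minus Ctrl PIP with SGC-CBP30 minus DMSO at r = 0.546. Genes are not independent replicates, so these correlations describe the libraries.

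The genes with the most values here were placed on mm10 by their annotation. Gzmb (gene ID 14939) lies on chromosome 14 from 56258836 to 56262334, Myc (17869) on chromosome 15 from 61985341 to 61990361, and Batf3 (381319) on chromosome 1 from 191098414 to 191108943. Slc7a5 (20539) lies on chromosome 8 from 121881146 to 121907686, Xcl1 (16963) on chromosome 1 from 164931644 to 164935522, Cd74 (16149) on chromosome 18 from 60803849 to 60812652, and Ifng (15978) on chromosome 10 from 118441046 to 118445894. Of the genes of mitochondria and fatty acids, Ppargc1a (19017) lies on chromosome 5 from 51454249 to 52115853, Ppargc1b (170826) on chromosome 18 from 61291445 to 61400756, and Cpt1a (12894) on chromosome 19 from 3322326 to 3385735. Each interval spans the annotated gene with its exons and introns.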

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

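The tests of transcript length and GC content, of a shared library batch and of other cell types were chosen after their results were seen, while the tests of sequencing depth and abundant genes were set beforehand. Genes with counts too low to be tested took 0.0385% of the counts in replicate 1 of EnPGC-1, above both DMSO libraries (0.0215% and 0.0193%) and all other libraries (0.0174% to 0.0214%).

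The replicates of DMSO and of EnPGC-1 differed along a shared axis: across genes, the difference between replicates 1 and 2 of DMSO correlated with that of EnPGC-1 at r = 0.666. The tables argue against the trend on transcript length and GC content as the whole cause. Removing each library's trend left r = 0.719 (0.817 before, on the same genes). Thinning all libraries to the smallest total left r = 0.672, and leaving out the 100 most abundant genes left r = 0.665. Those 2 steps could hardly move a correlation of normalized values across all genes, so they decide little. Rn18s-rs5 was highest in replicate 2 of DMSO (10073 CPM) and of EnPGC-1 (9044 CPM). A preparation or culture shared by libraries of the same number stays open, since no batch is labelled, while SGC-CBP30 deviated with DMSO (r = 0.23) and EnPGC-1 (0.23) in the same order, and Ctrl PIP against them (-0.25 and -0.23). The labels do not say whether replicates are separate animals or cultures, so a biological difference between them stays open, and no biological explanation was tested.

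When only the 4 libraries of SGC-CBP30 and Ctrl PIP were fitted, 1053 genes were called higher and 1241 lower, against 0 and 0 in the fit of all 8 libraries. With offsets for length and GC content 48.0% of those calls were kept in direction (1068 of the 2223 with a length and GC value, of them 426 higher and 642 lower). A trend of the libraries and an effect of the compound cannot be told apart, as the offsets also remove biology that tracks length or GC content. The common coefficient of variation of the 4 libraries was 0.159 against 0.415 over all 8, and a batch shared by the libraries of a group cannot be told apart from the compound, since no batch is labelled. An effect of SGC-CBP30 stays open beside these.

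B cell markers were higher with EnPGC-1 than with SGC-CBP30 (median log2 difference 2.22), though the cells were purified as CD8+ T cells by a method the labels do not name. Against DMSO, B cell markers had a median of 0.03 with EnPGC-1 and -2.17 with SGC-CBP30. Myeloid markers had -0.09 and -1.65, and erythroid and platelet markers 0.72 and -1.82. The difference thus lay mostly in lower markers with SGC-CBP30 than with DMSO. With Ctrl PIP, B cell and myeloid markers were below DMSO too (-1.25 and -1.16). A different share of B cells is a candidate explanation, since another set of 10 B cell genes had a median of 2.13. But it would not raise the erythroid (2.39) and myeloid (2.03, or 1.51 with members at 0 set to their bounds) markers. Ighm was at 799 against 812 CPM, far above Cd74 at 59.2 against 26.0 CPM. Such a level could hide a small share of B cells, so this single gene does not decide. A lower share of CD8+ T cells in the EnPGC-1 than in the SGC-CBP30 libraries would raise the markers of every other cell type alike. Dendritic cell markers had a median of 0.723, NK cell markers 0.28 (0.17 with bounds) and CD4 and regulatory T cell markers 0.08. Stromal and endothelial markers had -0.32 and CD8 T cell identity genes 0.21. Such a share and a difference in cells of only some types cannot be told apart. Of the stromal markers 3 of 7 were at 0 in a group, and the dendritic cell markers are 7. Members such as Klrk1 (30.6 CPM with SGC-CBP30) and Ikzf2 (149 CPM) have a baseline that would hide a small share. An effect of the compounds on these genes was not tested apart from cell shares.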

How the results depend on the processing

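The fits of 6 libraries, the offsets for transcript length and GC content, the surrogate variable, the crossed block and the list tests in 4 libraries were chosen after seeing the data, and the other alternatives were planned. In every comparison edgeR called 0 genes higher and 0 lower over all 8 libraries, and also with DESeq2 size factors, without a filter on low counts, with a log2 fold change of at least 1, with length and GC offsets, and when any 1 library was left out (0 to 0). limma on the rlog values also called 0 and 0. A group left with 1 library was then assumed to vary like the other groups. The cause was not tested for any of the changes listed here.

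DESeq2 called 5 genes higher and 13 lower for EnPGC-1 against DMSO, 0 and 1 for Ctrl PIP against DMSO, 7 and 52 for SGC-CBP30 against DMSO, 8 and 25 for EnPGC-1 against Ctrl PIP, 8 and 1 for EnPGC-1 against SGC-CBP30, and 6 and 24 for SGC-CBP30 against Ctrl PIP. In the same order, edgeR called 377 and 718, 1 and 0, 3089 and 3225, 5 and 36, 0 and 1, and 1036 and 1220 without the first libraries of DMSO and EnPGC-1. Without their second libraries it called 0 and 0, 1164 and 1201, 4 and 11, 2430 and 2753, 344 and 539, and 850 and 1016. With 1 surrogate variable it called 9 higher and 48 lower for SGC-CBP30 against DMSO, 2 and 0 for EnPGC-1 against Ctrl PIP, 4 and 18 for SGC-CBP30 against Ctrl PIP, and 0 and 0 in the other 3 comparisons. With only the 4 libraries compared it called 1053 and 1241 for SGC-CBP30 against Ctrl PIP, 615 and 854 with the offsets added, and 0 and 0 in the other 5 comparisons.

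Of the 38 lists, camera with the preset correlation called 1 higher and 19 lower for EnPGC-1 against DMSO, 4 and 5 for Ctrl PIP against DMSO, 1 and 18 for SGC-CBP30 against DMSO, 3 and 18 for EnPGC-1 against Ctrl PIP, 6 and 4 for EnPGC-1 against SGC-CBP30, and 0 and 16 for SGC-CBP30 against Ctrl PIP. In that order the counts were 0 and 1, 0 and 0, 0 and 2, 0 and 0, 0 and 0, and 0 and 1 with an estimated correlation, and 0 and 1, 0 and 0, 0 and 3, 0 and 1, 0 and 0, and 0 and 3 with fry. Leaving out 1 library gave 1 to 7 higher and 10 to 19 lower, 2 to 14 and 3 to 15, 1 to 7 and 14 to 19, 1 to 4 and 9 to 18, 5 to 10 and 0 to 7, and 0 to 2 and 15 to 20. With the first libraries of DMSO and EnPGC-1 left out, 2 lists were higher for EnPGC-1 against DMSO, 14 lower for Ctrl PIP against DMSO, 10 lower for EnPGC-1 against Ctrl PIP, 11 higher and 1 lower for EnPGC-1 against SGC-CBP30, and 1 higher for SGC-CBP30 against Ctrl PIP. Without the second, 3 were higher for EnPGC-1 against DMSO, 15 higher for Ctrl PIP against DMSO, 9 higher for SGC-CBP30 against DMSO and 11 lower for EnPGC-1 against SGC-CBP30. With the offsets 8 lists were lower for Ctrl PIP against DMSO, and in the fit of 4 libraries 2 were higher for EnPGC-1 against DMSO.

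The replicate number as a block gave 0 genes higher and 0 lower in every comparison. It gave 1 list higher and 19 lower, 4 and 7, 1 and 19, 3 and 18, 5 and 4, and 0 and 17, in the order used for the other list counts, and for EnPGC-1 against DMSO the lists called were the same. The labels do not say what the numbers mark, and not every pair of groups deviated together: deviations from the group mean correlated at 0.67 between DMSO and EnPGC-1, 0.23 between DMSO and SGC-CBP30 and 0.23 between EnPGC-1 and SGC-CBP30, but at -0.25, -0.23 and -0.04 for Ctrl PIP with these groups. With the numbers of Ctrl PIP exchanged, the block gave 0 genes higher and 0 lower in the comparisons with Ctrl PIP.

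For the named genes, 10082 values under the alternatives were set against 493 values of the report's fit. Of these, 185 had the other sign, 450 passed the threshold with the same sign and 1 passed it with the other sign. That 1 was Atp5k, an ATP synthase subunit, for Ctrl PIP against DMSO, whose log2 fold change of -0.28 became 0.79 without the second libraries of DMSO and EnPGC-1.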

Other observations

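The test of a shared response and the fits without both first or both second libraries of DMSO and EnPGC-1 were chosen after seeing the data, and the other list tests were planned. Those fits compare 1 library with 1 and take the spread from Ctrl PIP and SGC-CBP30 alone, so their p-values do not measure replication. For EnPGC-1 against DMSO, genes of the unfolded protein response had a median log2 fold change of -0.37 with 14 of 20 below 0 (camera adjusted p = 0.0043, and adjusted p = 0.49 with an estimated correlation), with Xbp1, its transcription factor, at -0.67 (SE 0.23). Genes of the ATF4 amino acid response had a median of -0.33 with 21 of 31 below 0 (camera adjusted p = 0.003, and adjusted p = 0.71 with an estimated correlation). Mitochondrial stress chaperones had a median of -0.49 with 10 of 11 below 0 (camera adjusted p = 4.4e-04, and adjusted p = 0.71 with an estimated correlation), with Hspa9, the mitochondrial HSP70, at -0.82 (SE 0.34). Without replicate 2 of DMSO these 3 lists were not called (camera adjusted p = 0.34, 0.82 and 0.96), and without replicate 1 of EnPGC-1 the first 2 were not (camera adjusted p = 0.21 and 0.070). Apoptosis regulators had a median of -0.20 (camera adjusted p = 0.0081, and adjusted p = 0.32 with an estimated correlation), lost without replicate 1 of DMSO or of EnPGC-1 (camera adjusted p = 0.10 and 0.21). Without both first or both second libraries of DMSO and EnPGC-1, the unfolded protein response was lower both times (camera adjusted p = 0.0015 and 0.014). The ATF4 response and the chaperones were lower only without the first (camera adjusted p = 3.7e-05 and 4.1e-08, against 0.16 and 0.40 without the second), and apoptosis regulators only without the second (camera adjusted p = 0.0014, against 0.083). Antioxidant genes had a median of -0.26 (camera adjusted p = 0.061). p53 targets had a median of -0.01 (camera adjusted p = 0.56), hypoxia genes of -0.39 (camera adjusted p = 0.075), xenobiotic response genes of 0.43 (camera adjusted p = 0.066) and lysosome and autophagy genes of 0.02 with a mean of -0.02 (camera adjusted p = 0.89). Single libraries decided some of these: antioxidant genes were called lower without replicate 1 of DMSO or of EnPGC-1 (camera adjusted p = 0.0068 and 0.012), and xenobiotic response genes higher without replicate 2 of EnPGC-1 (camera adjusted p = 0.010). Hypoxia genes were called lower without replicate 1 of DMSO or replicate 2 of EnPGC-1 (camera adjusted p = 3.4e-04 and 0.033) and higher without replicate 2 of DMSO (camera adjusted p = 0.028). Interferon-stimulated genes had a median of 0.12 against DMSO (camera adjusted p = 0.13, and 0.035, higher, without replicate 2 of EnPGC-1) and of 0.25 against Ctrl PIP with 28 of 36 above 0 (camera adjusted p = 0.012, and adjusted p = 0.73 with an estimated correlation), the latter lost without replicate 1 of EnPGC-1 or replicate 2 of Ctrl PIP (camera adjusted p = 0.46 and 0.67).

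In the same comparison, complex II to IV subunits had a median of -0.44 with 24 of 25 below 0 (camera adjusted p = 4.5e-04, and adjusted p = 0.74 with an estimated correlation). ATP synthase subunits had a median of -0.47 with 17 of 17 below 0 (camera adjusted p = 0.0012, and adjusted p = 0.74 with an estimated correlation). TCA cycle genes had a median of -0.22 with 21 of 23 below 0 (camera adjusted p = 0.0081, and adjusted p = 0.74 with an estimated correlation). Without replicate 2 of DMSO the first 2 lists were higher (camera adjusted p = 0.0078 and 0.013) and the TCA cycle was not called (camera adjusted p = 0.34), and without replicate 1 of EnPGC-1 none of the 3 was called (camera adjusted p = 0.92, 0.92 and 0.73). Replication-dependent histones had a median of -0.80 with 57 of 60 below 0 (camera adjusted p = 1.5e-05, and adjusted p = 0.74 with an estimated correlation), but were higher without replicate 2 of DMSO (camera adjusted p = 0.0022) and not called without replicate 1 of EnPGC-1 (camera adjusted p = 0.13). With both first or both second libraries of DMSO and EnPGC-1 left out, complex II to IV subunits (camera adjusted p = 1.2e-08 and 0.0068), ATP synthase subunits (camera adjusted p = 3e-07 and 0.0083) and histones (camera adjusted p = 1.3e-04 and 3.8e-08) were lower both times, and TCA cycle genes only without the first (camera adjusted p = 5.8e-04 and 0.16). Histone acetyltransferases and readers had a median of 0.07 (camera adjusted p = 0.41). Naive and memory genes had a median of 0.06 with a mean of -0.08 (camera adjusted p = 0.56), though Ly6c2 in that list was at -1.67 (SE 0.45). Naive and memory genes were called lower without replicate 2 of DMSO and higher without both first libraries of DMSO and EnPGC-1. Of the other cell types, erythroid and platelet markers were higher, with a median of 0.72 and 7 of 7 above 0 (camera adjusted p = 0.018, and adjusted p = 0.49 with an estimated correlation). They were the only list called higher, and were not called without replicate 1 of DMSO or of EnPGC-1 (camera adjusted p = 0.22 and 0.19). NK cell markers had a median of -0.67 with 9 of 12 below 0 (camera adjusted p = 0.0040, and adjusted p = 0.32 with an estimated correlation), not called without replicate 1 of DMSO (camera adjusted p = 0.17). Without both first or both second libraries, erythroid and platelet markers were higher only without the second (camera adjusted p = 0.16 and 0.034), and NK cell markers were not called (camera adjusted p = 0.062 and 0.069). Myeloid markers had a median of -0.09 with a mean of 0.13 (camera adjusted p = 0.41). Dendritic cell markers had a median of 0.14 and a test direction below 0 (camera adjusted p = 0.47), CD4 and regulatory T cell markers a median of 0.06 with a mean of -0.06 (camera adjusted p = 0.68), gamma-delta T cell markers of 0.27 (camera adjusted p = 0.41) and stromal and endothelial markers of 0.45 with a mean of -0.15 (camera adjusted p = 0.45). Without replicate 1 of EnPGC-1 myeloid and dendritic cell markers were called lower, and without replicate 2 gamma-delta T cell markers were called higher. Myeloid markers were called lower without both first libraries of DMSO and EnPGC-1 but higher without both second, so their direction depended on the libraries kept. CD4 and regulatory T cell markers were called higher without replicate 1 of DMSO and lower without replicate 2 (camera adjusted p = 0.048 and 0.0010).

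A hypothesis is that EnPGC-1 and SGC-CBP30 share part of their response. It was tested on comparisons with no library in common, where a shared control cannot raise the correlation across genes. Each library's trend on length and GC content was removed first. The lower of the 2 such correlations was then r = 0.471 (EnPGC-1 minus Ctrl PIP with SGC-CBP30 minus DMSO). The other was 0.732 (EnPGC-1 minus DMSO with SGC-CBP30 minus Ctrl PIP). A shared part would give such values. So could the axis along which replicates of DMSO and EnPGC-1 differ, which trend removal left in place (r = 0.719), and the test cannot separate them. The third way to split the groups gave -0.423 (EnPGC-1 minus SGC-CBP30 with Ctrl PIP minus DMSO). It is no further test, since its covariance follows from those of the other 2. Genes are not independent replicates and each group has 2 libraries, so a difference between libraries that happens to follow the same groups may contribute.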
